A study of Mus musculus with 6 samples.

How the data were processed

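DNA methylation was profiled by reduced representation bisulfite sequencing in 6 mouse lines of the OG2 strain: GSC (1 line), iPSC (2 lines), gPSC (2 lines) and ESC (1 line). DNA was isolated with a column kit and libraries were made by a sequencing company, per the labels' protocols. The submitters' processing notes name Bismark, Bowtie2, GATK and methylKit and the builds mm10 and GRCm38, per the submitters' processing notes without versions, roles or order. Settings of alignment and calling, coverage minimums and whether strands were merged are not given in the sources used here.

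The 5 libraries other than ESC have 10 tables, 1 for higher and 1 for lower methylation per library. Each table lists single positions with a p-value and a q-value, which the authors computed and deposited for each position. The third measurement is a methylation difference in percent points between the library and its reference, also deposited by the authors. Tested on the tables, every q was at most 0.01 and every absolute difference at least 25 points, so they hold called positions only, and positions that were measured but not called are not in them. Replicate lines have separate tables. The tables name no reference library; it is taken here to be the ESC library, the only sample without tables. Over the 10 pairs of libraries, positions listed in both libraries of a pair numbered 815782, a position being counted once for each such pair. Of these, 2939 (0.360%) had opposite directions. Among the opposite ones, 1 had differences more than 100 points apart, which 1 common reference would not allow. Neither coverage nor methylation levels are in the tables. The depth is therefore unknown, no interval for a position's difference can be given, and a position missing from a table can be unchanged or unmeasured.

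Coordinates are those of the tables, in GRCm38. Gene ends were taken from a GRCm38.p6 gene table of 34623 protein-coding and long non-coding genes that gives neither strand nor exons, so positions were not assigned to exons, introns or UTRs. The strand of a gene was inferred from the deposited feature column, which marks promoters and bodies of plus-strand genes, for 14545 genes, of which 5365 were plus and 9180 minus. Of 35 genes with textbook strands, 20 were assigned and 20 of these correctly. A promoter was the window from 2000 bp upstream to 500 bp downstream of the inferred start, and 5999 promoters held 3 or more positions listed in any table. A promoter or window was called hyper or hypo when it held at least 3 listed positions of that direction and at least 80% of its listed positions had it. For iPSC and gPSC the call had to hold in both lines. Values given for a promoter are means of the authors' differences over its listed positions, and group values are means and SDs over 2 lines.

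The promoters named in the text follow a rule. They are, for each cell type and direction, the 10 called promoters with the most listed positions, using the smaller number of the 2 lines for iPSC and gPSC, ties going to the larger mean difference, and leaving out predicted genes and small RNA genes. Every imprint window, up to 4 members of each list by the same ranking and any list member called in both lines of a kind were added. Of these, 2 ranked promoters and the result of the housekeeping list are not reported here. The 12 gene lists, of maternal and paternal imprinting control regions, pluripotency, germline, spermatogonial stem cell, lineage regulator, Hox, methylation machinery, 2-cell-like, fibroblast, testis somatic and housekeeping genes, come from textbook knowledge. The named-gene rule, lists, windows, thresholds, tests and a first set of alternatives were chosen before the data were examined. Imprint windows spanned 5000 bp to each side of the start for maternally methylated regions, and 7000 (H19), 20000 (Meg3) or 40000 bp (Rasgrf1) upstream to 1000 bp downstream for paternally methylated ones. All 20 windows fixed were searched. The start was the outermost one in the gene table. For 12 of these genes no strand could be inferred, and the strand known from textbooks was used. These strands were added after a first run, which had put the windows of plus-strand genes among them at the far end of the gene and had left out Nespas. The correction removed a hyper call of Peg10 in all 5 libraries and one of Zrsr1 in iPSC 2.

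Counts of listed positions and shares retained from GSC were compared between the 2 iPSC and 2 gPSC lines with a two-sided exact permutation test, whose smallest p is 0.333. The lines of a kind are independent cell lines per the series' design, and GSC has 1 library, so no comparison with GSC was tested. Wilson 95% intervals cover counting error only. Overlaps were set beside the overlap of independent lists, the product of the list sizes over the 448072 positions listed in any table or over the 5999 promoters. The positions measured in both libraries of a pair are not known. They can be more or fewer than those listed in any table, so the expected overlap of positions is no bound. A simulation of unchanged libraries against the same reference would need its reads, which are not analysed here. A gene list was given a percentile among 10000 random lists of the same size matched on listed positions, with no p-value, since genes are not replicates. Only members with an inferred strand and 3 or more promoter positions listed in any table could be assessed. These were 11 of 30 germline, 14 of 26 spermatogonial, 9 of 30 pluripotency and 17 of 38 lineage regulator genes. Of other lists, 13 of 39 Hox, 8 of 19 methylation machinery, 5 of 19 fibroblast and 4 of 15 testis somatic genes could be. Shares of assessed members are therefore not shares of the full lists.

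Positions 1 bp apart with opposite directions were frequent, and the counts are therefore also given without them, and without positions that have an opposite one within 50 bp. Both alternatives, and the restriction of retained shares to positions with another listed within 10 bp in every line, were chosen after seeing the data. Further alternatives were a difference of at least 50 points, q under 0.0001, autosomes only, windows of 1000 bp in place of positions, a match within 50 bp or in either direction, promoters from 1000 bp upstream to 200 bp downstream, 1 or 5 positions in place of 3, random lists without matching, leaving out each line, and pairing lines by number.

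The promoter calls were tested on simulated data of 5000 windows: all of 200 planted windows were recovered (100%), and 9.40% of windows with random directions were called. Planted windows held positions of 1 direction only and so met the rule by construction. Random directions were drawn for each position independently. In the libraries only 24.8% to 27.7% of pairs 2 bp apart were opposite, so the 9.40% need not hold for them. For retained shares, 40% planted over 100000 simulated positions returned 40%, which checks the counting only. Of 20000 simulated CpGs, removal of opposite neighbours took out 100% of planted pooled-strand positions and 0% of positions of 1 direction. Both members of each simulated pair passed the threshold together, which fixed these shares. They do not show how much stays where 1 member of a pair is not listed. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.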

Results

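Cytosine methylation was measured by reduced representation bisulfite sequencing, which reads the CpG-rich fragments of a digested genome, in 6 cultured mouse lines of the OG2 strain, whose cells carry a fluorescent reporter under Pou5f1 regulatory sequence. The cell types were germline stem cells (GSC, 1 line), the cultured counterpart of spermatogonial stem cells; induced pluripotent stem cells made from GSC with introduced transcription factors (iPSC, 2 independent lines); germline-derived pluripotent stem cells (gPSC, 2 independent lines); and embryonic stem cells (ESC, 1 line). The question named by the series title is whether cells reprogrammed with factors keep an epigenetic memory of their origin. Each of the 5 libraries other than ESC has a table of positions with higher methylation and a table of positions with lower methylation than a reference library that the tables do not name. It is taken here to be the ESC library, the only sample without tables, and is called the reference below. Positions with higher methylation are called hyper and those with lower methylation hypo. The tables give the difference in percentage points with its p and q, and neither coverage nor methylation levels, so the depth behind each value is unknown. At positions that differ by 100 points from the shared reference, where p depends on the reads alone, the median −log10 p was 3.81 in GSC, 3.48 in iPSC 1, 3.70 in iPSC 2, 3.48 in gPSC 1 and 3.30 in gPSC 2.

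Germline stem cells differed from the reference mainly by higher methylation, and at promoters by both higher and lower methylation. Methylation was lower at 5 promoters of genes that spermatogonial stem cells use. Foxo1, a transcription factor of stem cell maintenance (chromosome 3, 52266337 to 52268837), held 9 hypo positions with a mean difference of −60.0 points. Dmrt1, a regulator of male germ cell fate (chromosome 19, 25503618 to 25506118), held 9 with −55.3 points. Itga6, an integrin used to sort these cells, held 4 with −56.1 points, Gfra1, the GDNF co-receptor, 4 with −27.9 points, and Bcl6b, a GDNF-responsive repressor, 5 with −48.4 points beside 1 hyper position. These 5 of the 14 spermatogonial stem cell genes that could be assessed placed the list at percentile 97.9 of 10000 random lists matched on listed positions, and no member was called hyper. The list fell to percentile 89.0, with 4 members, once positions with an opposite one within 50 bp were left out, and to 90.6 when 1 position sufficed for a call. Percentiles were not adjusted for the number of lists, cell types and directions examined.

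Of 9 pluripotency promoters assessed in GSC, from a list of 30, 3 were called hyper and 1 hypo. Pou5f1, the POU factor at the centre of the pluripotency network (chromosome 17, 35504032 to 35506532), held 17 hyper positions and 1 hypo position with a mean difference of 66.9 points. The OG2 reporter carries upstream sequence of the same gene, so its copies can contribute reads to this window. Gdf3, a TGF-beta family ligand of pluripotent cells, held 6 hyper positions (49.2 points) and Zfp42, the Rex1 zinc finger protein, 3 (61.9 points). Tfcp2l1, a transcription factor of naive pluripotency, was called hypo with 4 hypo positions and 1 hyper position (−18.9 points). The 3 hyper members put the pluripotency list at percentile 84.5, below the 95th percentile set for naming a list.

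Among all genes, the promoter windows with the most hyper positions in GSC were Bcl3, a nuclear co-regulator of NF-kappaB (29 positions, 42.1 points), Tmem259 (27, 62.1 points), Speg, a striated muscle kinase (23, 55.2 points), and Wbscr25 (22, with 3 hypo, 46.0 points). Alpk3, a kinase of heart muscle (21, 64.2 points), Ccdc194 (20, 34.3 points), Chst5 (18, 50.03 points), Vsx1, a homeobox gene of the retina (18, 48.1 points), and Ltc4s, an enzyme of leukotriene synthesis (18, 46.2 points), followed. The most hypo positions were in Hivep1, a zinc finger transcription factor (24 positions, −84.8 points), Cds1, an enzyme of phospholipid synthesis (21, with 2 hyper, −41.9 points), Phf13, a chromatin reader (20, with 2 hyper, −62.3 points), and Appbp2os (20, with 5 hyper, −40.6 points). Sox12 (20, −42.8 points) and Wtap, a subunit of the RNA adenosine methyltransferase complex (20, −38.9 points), followed. Paqr9 (19, −78.3 points), Carm1, an arginine methyltransferase (19, −50.8 points), and Ago2, an Argonaute protein of RNA silencing (19, −40.0 points), each also held 1 or 2 hyper positions. Arl8a, a lysosomal GTPase (chromosome 1, 135144834 to 135147334), held 20 hypo positions with −48.2 points. In total 851 promoters were called hyper and 742 hypo in GSC.

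Over the whole genome, GSC had 211853 hyper positions with a median difference of 65.3 points and 43836 hypo positions with a median of −47.6 points, so that 82.9% of its listed positions were hyper. The authors' q compares 1 library with 1 reference library and GSC has 1 line, so these counts have no replicate check.

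Many hypo positions lay next to a hyper position. Listed positions 1 bp apart had opposite directions in 63.3% to 87.0% of pairs over the 5 libraries, and in 81.6% to 88.1% of these opposite pairs the 2 differences summed to within 5 points of 0. Pairs 2 to 5 bp apart were opposite less often (21.9% to 34.3%), but 80.7% to 91.6% of their opposite pairs summed to within 5 points of 0 too. Positions 1 bp from an opposite one made up 40.3% of the hypo positions in GSC, 43.6% and 32.8% in the iPSC lines and 48.2% and 48.4% in the gPSC lines, against 8.35%, 9.33%, 9.13%, 10.6% and 7.12% of hyper positions. Without them, 26151 hypo positions were left in GSC, 14259 in iPSC 1, 24610 in iPSC 2, 15324 in gPSC 1 and 10554 in gPSC 2. Leaving out every position with an opposite one within 50 bp left 21942, 11750, 20968, 12228 and 8650. The hyper counts fell to 190096, 104548, 115172, 117238 and 126714 under the same removal.

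**Figure D1:**
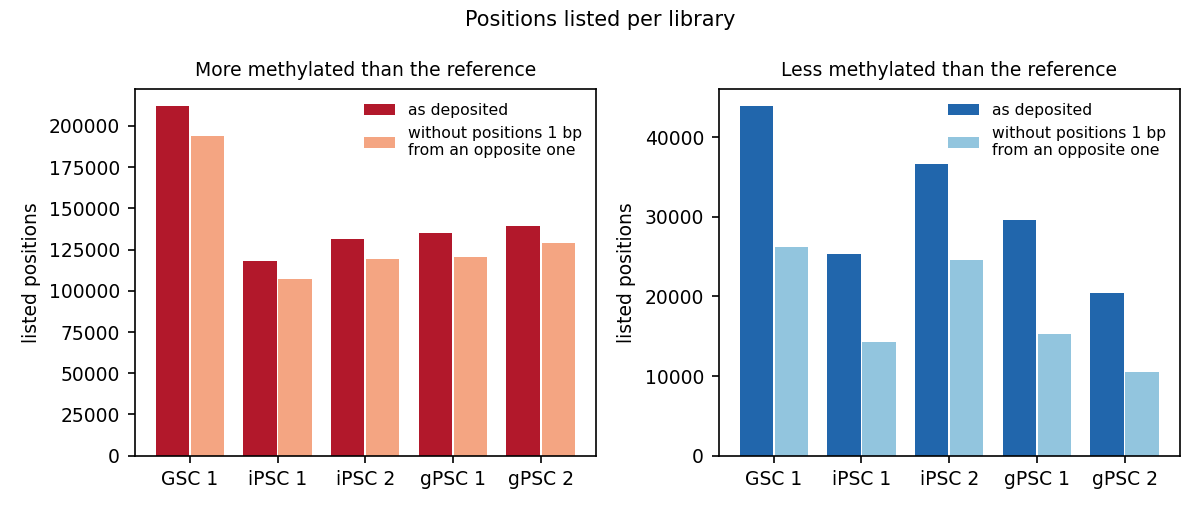
Number of listed positions (y axis) per library with higher methylation (left, red) and lower methylation (right, blue) than the reference, as deposited (dark bars) and without positions 1 bp from a position of opposite direction (light bars); each bar is 1 library, and the 2 panels have different y scales. Hyper positions as deposited range from 118235 in iPSC 1 to 211853 in GSC, and hypo positions from 20470 in gPSC 2 to 43836 in GSC.

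**Figure D2:**
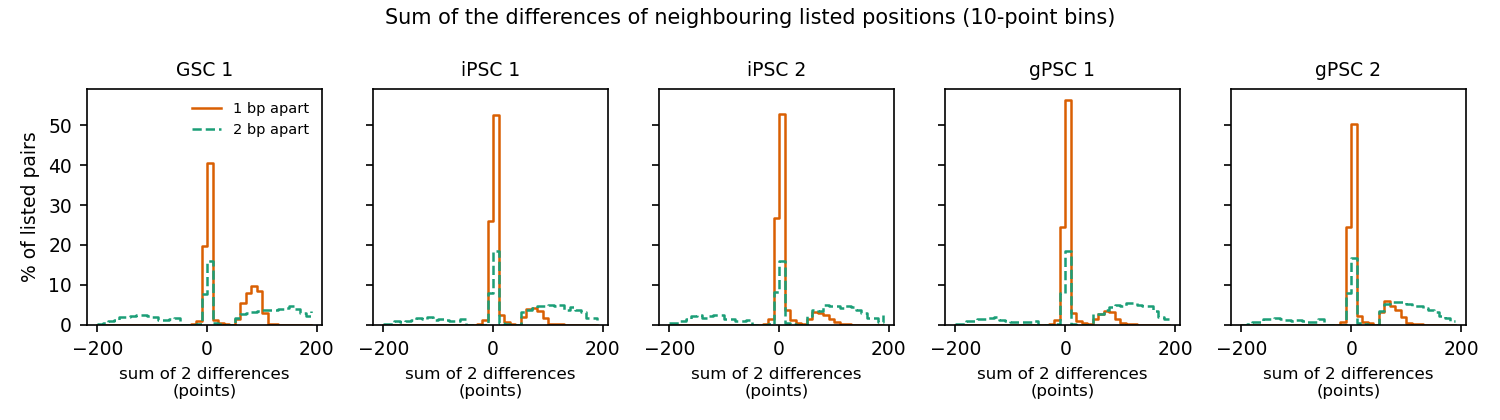
Sum of the 2 methylation differences of neighbouring listed positions (x axis, percentage points) against the share of pairs in each 10-point bin (y axis, %), for pairs 1 bp apart (solid orange) and 2 bp apart (dashed green), 1 panel per library. In every library the pairs 1 bp apart peak at 0, and at most 4.03% of their pairs with both positions hyper exceed 100 points by more than 5.

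The iPSC lines carried higher methylation than the reference at promoters of germline genes. Sycp3, a component of the synaptonemal complex (chromosome 10, 88457587 to 88460087), held 4 and 5 hyper positions in iPSC 1 and iPSC 2, with a mean difference of 43.4 ± 1.9 points (SD, n = 2). Asz1, a germ cell protein of piRNA biogenesis (chromosome 6, 18108561 to 18111061), held 8 and 3 (39.7 ± 9.4 points, SD, n = 2), Slc25a31, the testis ADP/ATP carrier (chromosome 3, 40706871 to 40709371), 7 and 3 (54.9 ± 1.4 points, SD, n = 2), and Mael, a protein of transposon silencing in germ cells (chromosome 1, 166238244 to 166240744), 6 and 5 (33.1 ± 4.8 points, SD, n = 2). These 4 of 11 germline genes assessed, from a list of 30, put the list at percentile 99.98 of random lists. None of the 11 was called hypo in both lines. In GSC, Mael and Slc25a31 had no listed position, Asz1 had 1 hyper and 3 hypo positions and Sycp3 had 1 hyper position.

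Pawr, a pro-apoptotic regulator (chromosome 10, 108330189 to 108332689), had the most hyper positions in iPSC, 16 in each line with 52.0 ± 4.2 points (SD, n = 2). Pou4f1, a transcription factor of sensory neurons (chromosome 14, 104467618 to 104470118), held 14 in each iPSC line (54.0 ± 8.8 points, SD, n = 2), whereas gPSC 1 had 1 hypo position there and gPSC 2 none, and GSC had 14 hyper beside 17 hypo positions. Purg and Wrn, the Werner syndrome helicase, have overlapping windows on chromosome 8 with the same 14 hyper positions in each iPSC line (46.4 ± 13.2 points, SD, n = 2). Tlk1, a kinase of chromatin assembly (chromosome 2, 70825316 to 70827816), held 14 and 13 positions in the iPSC lines (38.3 ± 4.8 points, SD, n = 2) and 1 position of each direction in GSC. Colgalt2, Wnt5a, a ligand of non-canonical Wnt signalling, Vmn2r29, a vomeronasal receptor, and Gas2l2 followed, with mean differences of 51.4 ± 8.1, 64.9 ± 10.8, 42.9 ± 3.9 and 43.9 ± 5.5 points (SD, n = 2). All of these except Pou4f1, Tlk1 and Wrn were also called hyper in GSC.

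Fewer promoters had lower methylation than the reference in both iPSC lines. Arl8a held 20 hypo positions in each line (−48.3 ± 0.3 points, SD, n = 2), the same number as in GSC. Tent4b, a non-canonical poly(A) polymerase, held 17 and 16 (−44.5 ± 10.5 points), a call that ended once positions with an opposite one within 50 bp were left out. Mta1, a subunit of the NuRD complex, held 14 and 15 (−42.5 ± 2.4 points), Rpl26, a ribosomal protein, 14 and 13 (−45.7 ± 6.7 points), and Dnaja2, a co-chaperone, 12 and 12 (−60.1 ± 1.0 points). Cyb5r4, an oxidoreductase, held 9 hypo positions with −82.3 points in each iPSC line and in gPSC 2, and −78.4 points in gPSC 1. Levels are not listed and the reference library is shared. Such equal values can therefore reflect the level of the reference, and a small SD is not independent evidence from the lines. Nmd3, an export adaptor of the large ribosomal subunit, held 7 and 14 (−89.9 ± 2.9 points), Zbed4 16 and 9 (−61.5 ± 11.4 points), Pgbd5, a gene derived from a transposase, 9 and 9 (−47.9 ± 11.7 points), and Slc2a1, a glucose transporter, 8 and 9 (−28.6 ± 0.3 points). In all, 186 promoters were called hyper in both iPSC lines and 38 hypo, where the single lines had 445 and 441 hyper and 250 and 403 hypo. The count of hypo promoters was 62 when positions 1 bp from an opposite one were left out.

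Listed positions averaged 124900 ± 9426 hyper and 30962 ± 8021 hypo (SD, n = 2) in iPSC. Median differences were 49.8 and 56.5 points for hyper and −42.6 and −53.6 points for hypo positions in iPSC 1 and iPSC 2.

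The gPSC lines, obtained from germline cells without the reprogramming factors, also carried higher methylation at germline genes. Sycp3 held 15 and 8 hyper positions in gPSC 1 and gPSC 2 (47.3 ± 17.4 points, SD, n = 2), Asz1 9 and 5 (44.2 ± 4.4 points, SD, n = 2), and Dazl, an RNA-binding protein required for germ cell development (chromosome 17, 50293120 to 50295620), 15 and 8 with 1 hypo position in each (44.7 ± 3.6 points, SD, n = 2). Taf7l, a germ cell paralogue of a TFIID subunit (chromosome X, 134476005 to 134478505), held 9 and 3 (39.9 ± 2.3 points, SD, n = 2), and Tex19.1, which restrains retrotransposons in germ and pluripotent cells (chromosome 11, 121144143 to 121146643), 7 and 3 (46.1 ± 4.6 points, SD, n = 2). These 5 of 11 put the germline list at percentile 99.99. Another member, Ddx4, a germ cell helicase, was hypo in gPSC 2 alone (6 hypo positions and 1 hyper, −65.9 points). Tex19.1 was also hyper in GSC (4 positions, 55.7 points), while the Dazl window held 6 hyper and 14 hypo positions there.

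The gene with the most hyper positions in gPSC was again Pawr (16 and 15 positions, 43.9 ± 4.8 points, SD, n = 2), followed by Ctnnd1, a catenin that binds cadherins (15 and 13, 56.0 ± 4.8 points), and Tlk1 (14 and 13, 32.8 ± 1.5 points). Kif26b, a kinesin family member, had 12 and 12 (28.3 ± 7.6 points), Colgalt2 10 and 10 (59.2 ± 11.5 points), Vmn2r29 12 and 10 (40.4 ± 10.7 points) and Tuba3b, an alpha-tubulin of the testis, 11 and 9 (49.8 ± 3.2 points). Rpl39l, a ribosomal protein of male germ cells, had 9 and 12 (48.5 ± 3.9 points), Saysd1 9 and 9 (36.2 ± 6.5 points) and Efcab14 8 and 8 (68.2 ± 3.1 points). Efcab14 had no listed position in either iPSC line and 8 hyper positions in GSC.

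Hypo promoters of both gPSC lines included Tent4b (16 and 15 positions, −45.5 ± 4.4 points, SD, n = 2), Mta1 (19 and 14, −52.0 ± 2.4 points) and Rpl26 (14 and 13, −45.2 ± 10.5 points). Ppp2r2d, a regulatory subunit of a protein phosphatase (12 and 10, −43.6 ± 8.4 points), Cyb5r4 (10 and 9, −80.4 ± 2.8 points), Trmt61b, a mitochondrial tRNA methyltransferase (10 and 9, −38.6 ± 1.1 points), Slc2a1 (9 and 9, −23.9 ± 6.2 points) and Nmd3 (8 and 7, −72.5 ± 27.4 points) were among them too. Tcea2, a transcription elongation factor, held 7 hypo positions in each gPSC line (−81.7 ± 1.5 points) and 7 in GSC, against 3 hyper in iPSC 1 and 7 of each direction in iPSC 2. Fam160b1 (chromosome 19, 57358923 to 57361423) held 12 and 11 hypo positions in gPSC (−49.8 ± 2.4 points) and 4 hyper positions in GSC (86.5 points), none of them the same. Its promoter was hypo in iPSC 1 too (3 positions, −53.2 points). Both gPSC lines together had 242 hyper promoters and 31 hypo, the latter 49 without positions 1 bp from an opposite one, where the single lines had 518 and 591 hyper and 277 and 246 hypo. Listed positions averaged 137086 ± 2948 hyper and 25026 ± 6443 hypo (SD, n = 2). Median differences were 56.4 and 50.5 points for hyper and −44.4 and −43.1 points for hypo positions in gPSC 1 and gPSC 2.

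**Figure D3:**
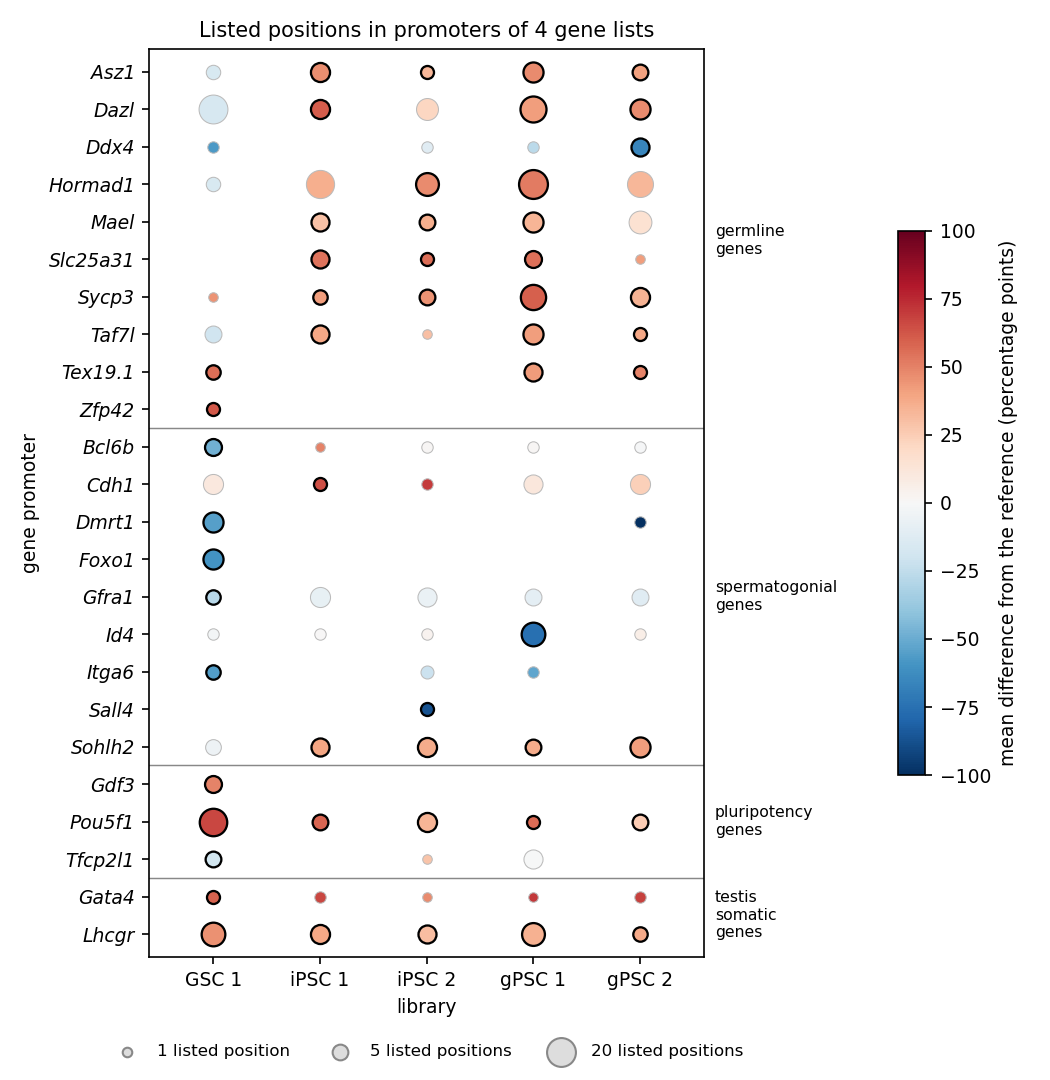
Promoters of germline, spermatogonial, pluripotency and testis somatic genes (y axis) in the 5 libraries (x axis); dot area grows with the number of listed positions, colour gives their mean difference from the reference in percentage points, a black outline marks a promoter call, and a gene in several lists is drawn once. Sycp3 and Asz1 are outlined as hyper in the 4 iPSC and gPSC lines and not in GSC, while Foxo1 and Dmrt1 are outlined as hypo in GSC alone.

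The 2 kinds of pluripotent line were compared to ask whether introduced factors leave another methylation state than conversion in culture. Promoter calls overlapped between them: Pawr, Tlk1, Colgalt2, Vmn2r29, Sycp3 and Asz1 were among 102 promoters hyper in all 4 lines, and Mta1, Rpl26, Cyb5r4, Slc2a1 and Nmd3 among 11 hypo in all 4. Independent lists of these sizes would share 7.5 and 0.196 promoters among those with 3 or more listed positions in any table. No promoter was hyper in both lines of one kind and hypo in both of the other, and no single position was. Only 1 promoter became opposite, hypo in iPSC and hyper in gPSC, when positions 1 bp from an opposite one were left out, and none when the distance was 50 bp. All tables share the reference library and its reads cannot be split here, so part of the overlap may come from it.

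The mean number of hyper positions was lower in iPSC than in gPSC (difference −12185), with each iPSC line below each gPSC line. The two-sided exact permutation test over the 4 lines gave p = 0.333, the smallest value that 2 against 2 lines allow. The lines overlapped with a difference of at least 50 points (−7330) and in 1000 bp windows (−1813), where the exact permutation p was 0.667. Hypo positions were more numerous in iPSC by 5936, with overlapping lines (exact permutation test, two-sided, p = 0.667). The median difference of hyper positions was 53.1 ± 4.76 points in iPSC and 53.4 ± 4.18 in gPSC (SD, n = 2), and that of hypo positions −48.1 ± 7.77 and −43.8 ± 0.944.

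To address memory of the cell of origin, GSC positions were looked up in each line. Of the hyper positions of GSC, 32.7% (95% Wilson interval 32.5 to 32.9) were also hyper in iPSC 1, 35.5% (35.3 to 35.7) in iPSC 2, 42.1% (41.9 to 42.3) in gPSC 1 and 37.7% (37.5 to 37.9) in gPSC 2. The intervals cover counting error only, since neighbouring positions share reads. The share averaged 34.1 ± 2.01% in iPSC and 39.9 ± 3.13% in gPSC (SD, n = 2), a difference of −5.80 points with each iPSC line below each gPSC line (exact permutation test, two-sided, p = 0.333, the smallest value possible). At the hypo positions of GSC the shares were 18.3% (17.9 to 18.7), 20.4% (20.04 to 20.8), 25.2% (24.8 to 25.6) and 13.5% (13.1 to 13.8), or 19.4 ± 1.5% in iPSC and 19.3 ± 8.31% in gPSC (SD, n = 2; exact permutation test, two-sided, p = 1). The hyper separation depended on the size of each line's list. Of the line's own hyper positions, GSC shared 58.5% and 57.2% in iPSC and 66.1% and 57.4% in gPSC. By this measure the lines overlapped (exact permutation test, two-sided, p = 0.667).

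Leaving out either iPSC 2 or gPSC 2 turned the hypo difference of 0.0217 points to −1.04 or −5.85 points, and it was −0.0829 points on autosomes and −0.495 points at q under 0.0001. Positions of opposite direction within 50 bp also mattered for it: without them the iPSC share was 11.6% and the gPSC share 10.2%. Shared hyper positions numbered 1.24, 1.21, 1.40 and 1.21 times those of independent lists drawn from all listed positions, and shared hypo positions 3.24, 2.50, 3.82 and 2.95 times, in iPSC 1, iPSC 2, gPSC 1 and gPSC 2. Independent lists are not a value for no memory, since all tables share 1 reference library, whose own error can raise every overlap with GSC. The positions measured in both libraries are not known either, so these ratios can be too high or too low. At most 0.484% of GSC positions of a direction were listed in the opposite direction in a line. A GSC position missing from a line's table was either not different from the reference or not measured there, and the tables cannot separate these.

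**Figure D4:**
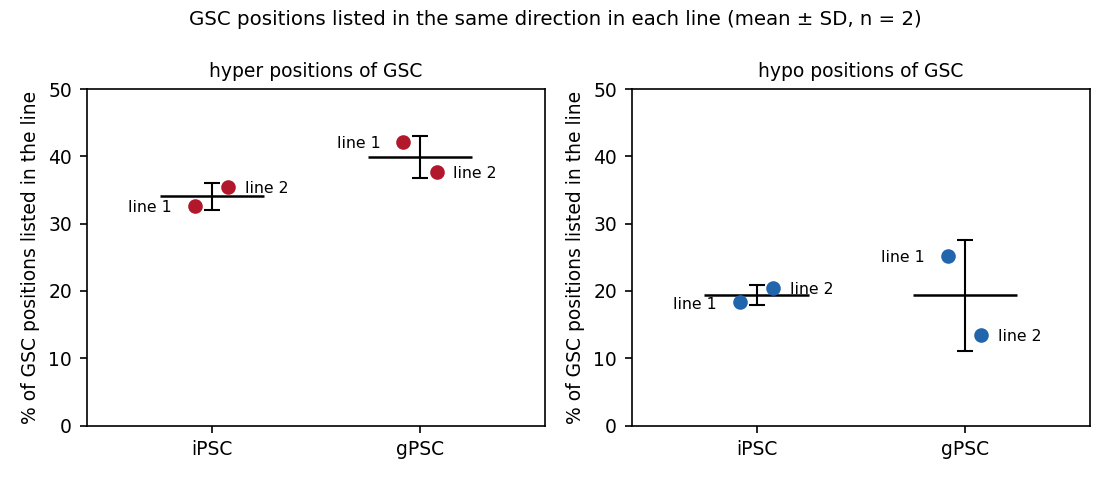
Share of the hyper (left, red) and hypo (right, blue) positions of GSC listed in the same direction in each line (y axis, %), by kind of line (x axis); points are single lines, horizontal bars the mean and error bars 1 SD of 2 lines. The hyper shares are 32.7% and 35.5% in iPSC and 42.1% and 37.7% in gPSC, and the hypo shares of the gPSC lines, 25.2% and 13.5%, enclose those of iPSC.

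By gene, 127 of the 186 hyper promoters of iPSC and 166 of the 242 of gPSC were also hyper in GSC, where independent lists would share 26.4 and 34.3. Part of these overlaps may come from the shared reference library, so they do not measure memory of origin by themselves. Colgalt2, with 10 hyper positions in each of the 5 libraries, Gas2l2, Vmn2r29, Pawr, Lhcgr and Pou5f1 were among them in both kinds of line. For hypo promoters 16 were shared with iPSC and 12 with gPSC, against 4.7 and 3.83 for independent lists, among them Arl8a and Dnaja2 in iPSC, Tcea2 and Trmt61b in gPSC, and Mta1, Rpl26 and Slc2a1 in both. Arl8a and Dnaja2 were also hypo in gPSC 2, and gPSC 1 held 20 and 12 hypo positions there beside 10 hyper ones each. Without positions that have an opposite one within 50 bp, Arl8a was hypo in both gPSC lines. Trmt61b was also hypo in iPSC 2. Pou5f1 held 5 and 7 hyper positions in the iPSC lines (45.8 ± 17.2 points, SD, n = 2) and 3 and 4 in the gPSC lines (41.1 ± 22.4 points), fewer than the 17 of GSC. Its gPSC call ended without positions that have an opposite one within 50 bp.

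Where GSC and a line listed the same position, the common reference cancels from the difference between them. At shared hyper positions the lines were less methylated than GSC, with median differences of −9.52 points in iPSC 1, −8.33 in iPSC 2, −6.84 in gPSC 1 and −7.90 in gPSC 2, from 69204, 75232, 89206 and 79826 positions. Shared hypo positions differed from GSC by medians of −0.454, 0, 1.43 and −0.610 points. Between lines, the medians at shared hyper positions lay between −0.639 points (gPSC 2 minus gPSC 1) and 2.88 points (gPSC 1 minus iPSC 1). Only positions past the authors' thresholds in both tables enter here, which limits how far such values can differ.

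Neither pair of lines of the same kind led the mixed pairs in the overlap of hyper positions. The largest overlap was between iPSC 1 and gPSC 2, which held 46.8% of their joint hyper positions in common, against 32.8% for the iPSC pair, 35.1% for the gPSC pair and 34.5% to 35.2% for the other mixed pairs. Positions hyper in both iPSC lines and neither gPSC line numbered 3447, and those in both gPSC lines and neither iPSC line 10124. The other ways to pair the lines gave 20572 (iPSC 1 with gPSC 2) and 11500 (iPSC 2 with gPSC 1), and 7653 (iPSC 1 with gPSC 1) and 7701 (iPSC 2 with gPSC 2). Of the positions hyper in all 4 lines, 36329, GSC shared 85.6%, whereas GSC shared 26.1% of those exclusive to iPSC 1 and gPSC 2. For hypo positions the iPSC pair had 1886, the gPSC pair 1423 and the mixed pairs 1381 to 3303, and 2538 were common to all 4 lines. Without positions that have an opposite one within 50 bp, the hypo counts of the iPSC and gPSC pairs fell to 927 and 384. With 3 pairings of 4 lines no share under 0.05 can be reached, so no test was made.

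Imprinting control regions, which keep methylation from one parent, were examined in windows around 20 genes. In every library 78.2% to 87.2% of all listed positions were hyper. How often other windows of these sizes would be called hyper was not computed. Hyper calls, above all in the widest window, that of Rasgrf1, can therefore come from this background alone. At paternally methylated regions, Rasgrf1 (chromosome 9, 89869508 to 89910508) was hyper in all 5 libraries, with 7 positions, 1 opposite one and a mean of 39.2 points in GSC and 3 to 7 positions with 42.2 to 54.9 points in the lines. H19 (chromosome 7, 142577146 to 142585146) was hyper in GSC (4 positions, 72.6 points) and gPSC 1 (3, 43.1 points), and Meg3 (chromosome 12, 109520996 to 109541996) in iPSC 1, gPSC 1 and gPSC 2 with 3 positions each (56.9, 83.3 and 55.5 points). In the windows set for maternally methylated regions, Inpp5f (chromosome 7, 128606181 to 128616181) was hyper in iPSC 1, gPSC 1 and gPSC 2 with 9, 10 and 11 positions (31.0, 28.3 and 47.3 points) and not in iPSC 2 or GSC.

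Nap1l5 (chromosome 6) was hyper in GSC, iPSC 1 and gPSC 2 with 3 positions each, and Slc38a4 (chromosome 15) in GSC with 4. Peg13 (chromosome 15) was hyper in iPSC 2 (10 positions) and gPSC 1 (4, with 1 hypo), and Gnas (chromosome 2) in gPSC 1 (3). Plagl1 (chromosome 10, 13085832 to 13095832) was the only window called hypo, in gPSC 2 (5 positions, −71.4 points); gPSC 1 had 10 hypo and 3 hyper positions there, and without positions 1 bp from an opposite one both gPSC lines were hypo, but not without those within 50 bp. Nespas (Gnasas1 in the gene table) had 1 to 9 hyper and 1 to 10 hypo positions in each library and no call. Grb10, Zrsr1, Airn, Impact, Mcts2 and Mest had listed positions without a call, and Snrpn, Kcnq1ot1, Peg3 and Peg10 had none in any library. The windows lie at the outermost start of each gene, so control regions at inner promoters, as in Snrpn and Inpp5f, can lie outside them, and the calls of Inpp5f need not concern its imprinted region. Together 4 windows were hyper in GSC, 1 in both iPSC lines and 3, Inpp5f included, in both gPSC lines. With 1 position sufficient for a call these counts were 8, 4 and 6, and with 5 required 1, 0 and 2.

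The remaining gene lists did not reach the 95th percentile in any cell type. Of 4 assessed testis somatic genes, Gata4, a gonadal transcription factor (3 positions, 58.8 points), and Lhcgr, the receptor for luteinising hormone (13, 45.5 points), were hyper in GSC (percentile 92.6), and Lhcgr was hyper in both iPSC lines (34.7 ± 5.6 points, SD, n = 2, percentile 87.6) and both gPSC lines (36.6 ± 1.4 points, percentile 83.0). Sohlh2, a transcription factor of spermatogonial differentiation (chromosome 3, 55180044 to 55182544), was the 1 spermatogonial member called in both lines of a kind, hyper in iPSC (38.2 ± 1.5 points, SD, n = 2, list percentile 62.2) and in gPSC (39.5 ± 3.3 points, percentile 55.3). In single lines, Cdh1 was hyper in iPSC 1, Sall4 hypo in iPSC 2 and Id4 hypo in gPSC 1. Of 17 lineage regulators, Hand1 (11 positions, 56.2 points) and Gata4 were hyper and Gsc, the goosecoid homeobox gene, hypo (5, −63.7 points) in GSC. Lhx5 was hypo in iPSC (−34.0 ± 3.8 points, SD, n = 2) and Neurog1 hyper in gPSC (37.4 ± 0.9 points, SD, n = 2). Lhx5 was hypo in gPSC 1 too (3 positions, −30.3 points), and Neurog1 hyper in iPSC 2 (4, 82.4 points). Neurog1 was also hyper in GSC once positions 1 bp from an opposite one were left out. The highest percentile for lineage regulators was 88.8, for Lhx5 in iPSC.

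Hox genes, with 13 assessed, had 1 hyper (Hoxc10) and 1 hypo (Hoxd1) member in GSC and none called in both lines of a kind. Among single lines, Hoxb9 was hyper in iPSC 2 and gPSC 2, Hoxc10 in iPSC 2 and Hoxd1 in iPSC 1. Hoxc13 was hypo in iPSC 1 and Hoxc6 in gPSC 1. Of 8 genes of the methylation machinery, Ehmt1, a histone methyltransferase, and Dnmt3l, the cofactor of de novo methylation, were hyper and Mbd2, a methyl-CpG-binding protein, hypo in GSC (highest percentile 73.3), and none was called in both lines of a kind. Fibroblast genes, which would mark feeder cells, had 1 of 5 members called in GSC, Twist2, hyper (percentile 39.2). None was called in both lines of a kind. In single lines, Twist2 was hypo in iPSC 2 (4 hypo positions and 1 hyper, −42.3 points) and Fn1 in gPSC 1 (3, −72.7 points). The imprinted lists had 3 maternal and 1 paternal gene assessed and no promoter call in GSC or in both lines of a kind; Plagl1 was hypo in both gPSC lines without positions 1 bp from an opposite one (percentile 97.3) and not without those within 50 bp (percentile 0). None of the genes of the 2-cell-like list could be assessed.

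Hypo positions concentrated in promoters and hyper positions outside them. Promoters held 43.0% of the hypo positions in GSC, 33.8 ± 4.34% in iPSC and 39.2 ± 0.392% in gPSC (SD, n = 2). They held 8.40%, 8.04 ± 0.254% and 8.34 ± 1.46% of the hyper positions, and 16.5% of the positions listed in any table. Without positions that have an opposite one within 50 bp, the hyper shares in promoters were 4.28%, 3.99% and 4.38%, and the hypo shares 39.8%, 28.8% and 35.1%. Gene bodies outside promoters held 57.4% of the hyper positions in GSC and 52.9% to 55.0% in the lines.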

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

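None of the results below was tested as a difference, since GSC has 1 library, and the genes were chosen after their values were seen. They stand out because a promoter was called one way in GSC and the opposite way in every line of a kind. The calls rest almost wholly on different positions of the window: the only position listed in opposite directions in GSC and a line of that kind was 1 in Lrrc43, in iPSC 2. They are therefore not reversals at the same positions, and the GSC positions can be missing from the lines' tables. All 4 GSC positions of 4930467D21Rik lay 1 bp from a hyper position of gPSC 1, and 2 of them 1 bp from one of gPSC 2.

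For hypo in GSC and hyper in every iPSC line there were 2 such promoters. Lrrc43 (chromosome 5, 123487287 to 123489787) had −38.5 points over 3 positions in GSC and 43.6 ± 2.10 points in iPSC (SD, n = 2), with gPSC 2 also hyper (47.2 points). Pcgf5, a Polycomb group RING finger protein (chromosome 19, 36346329 to 36348829), had −42.8 points in GSC over 11 hypo positions and 1 hyper position, and 66.5 ± 1.91 points in iPSC over 4 and 5 positions, with gPSC 2 at 66.6 points and no listed position in gPSC 1.

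Only 1 promoter was hyper in GSC and hypo in every gPSC line, Fam160b1 (chromosome 19, 57358923 to 57361423), with 86.5 points over 4 positions in GSC and −49.8 ± 2.40 points in gPSC (SD, n = 2). It was also called hypo in iPSC 1 (3 positions, −53.2 points). For hypo in GSC and hyper in every gPSC line there were 2. The first, 4930467D21Rik (chromosome 5, 97390417 to 97392917), had −85.6 points over 4 positions in GSC and 55.0 ± 1.33 points in gPSC (SD, n = 2), and Atf7ip2 (chromosome 16, 10190649 to 10193149) had −69.4 points over 3 positions and 41.0 ± 10.5 points. At 4930467D21Rik, iPSC 2 was also called hyper (12 hyper positions and 1 hypo, 43.1 points). All 5 calls persisted without positions 1 bp, or within 50 bp, of an opposite one, but the counts depended on this choice. Removal at 1 bp added Galnt2 (hyper in GSC, hypo in iPSC) and Dazl (hypo in GSC, hyper in gPSC). Removal within 50 bp raised the count of promoters hypo in GSC and hyper in the lines to 4 for iPSC, with Foxd3 and Dazl, and to 4 for gPSC, with Eloa and Dazl. At single positions, 25 were hyper in GSC and hypo in all 4 lines and 12 the reverse.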

How the results depend on the processing

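Of 302 values recomputed, 168 stayed on the same side of their threshold or within the spread or 1.5 times the count, 128 moved further, 2 dropped below the 95th percentile and 4 changed sign. The 168 include all 22 differences in listed positions between iPSC and gPSC. Their threshold was p under 0.05 in the exact tests, which 2 against 2 lines cannot reach. Only a change of sign could therefore have moved them, and the same holds for the differences in retained shares. The depth of the libraries is unknown and limits which positions were listed at all. The alternatives on opposite neighbours and on positions listed within 10 bp were chosen after seeing the data. Counts fell under stricter thresholds by construction, and the cause of the other shifts was not tested.

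With a difference of at least 50 points, hyper positions were 68343 in iPSC and 75673 in gPSC, hypo positions 20423 in GSC, 14766 in iPSC and 10200 in gPSC. Retained hyper shares were 27.6% (iPSC) and 33.4% (gPSC), the retained hypo share of iPSC 13.2%, positions of the iPSC and gPSC pairs 1690 and 6488 hyper, 567 and 436 hypo, hyper promoters 54 and 69, and hyper imprint windows 0 in both.

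At q under 0.0001, hyper positions were 141184, 69247 and 84516 and hypo positions 19296, 11219 and 10092 in GSC, iPSC and gPSC. Retained hyper shares were 28.7% and 36.5%, and the hypo difference turned to −0.495 points, as it did on autosomes (−0.0829). The iPSC pair had 1638 hyper and 651 hypo positions and the gPSC pair 516 hypo. Promoters were 65 and 93 hyper, 274 hypo in GSC and 12 hypo in each kind of line, and hyper imprint windows 2 in GSC and 0 in iPSC.

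As 1000 bp windows, hyper counts were 20271, 10473 and 12286 and hypo counts 1647, 799.5 and 574.5. The retained hyper share of iPSC was 32.0%, the hypo shares 7.86% and 6.44%, and pair counts 281 and 940 hyper, 38 and 24 hypo. A match within 50 bp gave 46.8% and 53.5% (hyper) and 30.8% and 30.2% (hypo), and positions with another listed within 10 bp in every line 65.4% and 70.4%, 68.1% and 64.3%.

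Without positions 1 bp from an opposite one, hypo positions were 26151, 19434.5 and 12939, the retained hypo share of iPSC 13.4%, hypo pair counts 1150 and 548, hypo promoters 62 and 49, and hypo imprint windows in gPSC 1. Promoters held 4.77%, 4.50% and 4.85% of hyper and 39.4%, 28.6% and 34.4% of hypo positions. With the distance set to 50 bp, hypo positions were 21942, 16359 and 10439, retained hypo shares 11.6% and 10.2%, hypo pair counts 927 and 384, the spermatogonial list at percentile 89.0 (1 member fewer), and promoter shares 4.28%, 3.99% and 4.38% of hyper and 39.8%, 28.8% and 35.1% of hypo positions.

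Promoters from 1000 bp upstream to 200 bp downstream gave 474, 93 and 120 hyper and 18 hypo in iPSC. A minimum of 1 position gave 2462, 863 and 1100 hyper, 2027, 571 and 347 hypo, imprint windows 8, 4 and 6 hyper and 1 hypo in GSC, and the spermatogonial list at 90.6. A minimum of 5 gave 395, 62 and 82 hyper, 19 and 17 hypo in iPSC and gPSC, and imprint windows 1 in GSC and 0 in iPSC.

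Leaving out 1 line in turn, counts of positions exclusive to a kind ran from 12341 to 41355 hyper and 2926 to 24809 hypo for iPSC and from 22203 to 45854 hyper and 2395 to 16582 hypo for gPSC, since a single line then stood for a kind. Promoters ran from 441 to 445 hyper and 250 to 403 hypo in iPSC and from 518 to 591 and 246 to 277 in gPSC. The retained hypo difference ran from −5.85 to 5.90 points, while the hyper difference kept its direction (−8.02 to −3.59). That direction was fixed in advance, since each iPSC line retained a smaller hyper share than each gPSC line.

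With the line number as a replicate block, the paired exact sign-flip tests gave −12185 hyper positions (p = 0.5), 5936 hypo positions (p = 1), −5.80 points retained hyper (p = 0.5) and 0.0217 points retained hypo (p = 1). The smallest p of 2 pairs is 0.5, and the lines share only a number.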

Other observations

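All tests of explanations in this part were chosen after the result was seen. Some promoters were called in all 4 pluripotent lines and not in GSC: 24 were hyper and 4 hypo. Besides Sycp3, Asz1, Sohlh2, Tlk1 and Rpl39l, the hyper group, named here after its values were seen, held Cd48, a surface protein of blood cells (3 to 10 hyper positions per line, with 9 hyper and 5 hypo in GSC), Ccdc146, a gene of sperm flagella (7 in each line), Pabpc2, a poly(A)-binding protein of germ cells (3 to 7), Usp9y, a Y-linked deubiquitinase (3 or 4), Tmem100 (3 or 4), Necab1 (3 or 4) and Ppfia2, a synaptic scaffold gene (3 to 5). Ccdc146, Usp9y, Necab1 and Fam185a had no listed position in GSC. The 4 hypo promoters were Nmd3, Tent4b, Cyb5r4 and 2010109A12Rik, and in Nmd3 the 2 positions listed in GSC were both hyper. Tent4b held 17 hypo and 5 hyper positions in GSC (−30.6 points). Without positions 1 bp from an opposite one, GSC was called hyper at Cd48 and hypo at Tent4b, so both left the group. Without those within 50 bp, Cd48 was back in it and the iPSC call of Tent4b ended.

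Positions 1 bp apart were listed with equal and opposite differences in every library, and the fewer opposite pairs 2 to 5 bp apart summed to near 0 about as often. A candidate explanation is that reads of both strands were counted together at each position, so that a shift in strand balance moves neighbouring cytosines in opposite directions. Then 2 hyper neighbours could not sum to much over 100 points, and at most 4.035% of such pairs exceeded 100 points by more than 5, against 50.9% to 67.9% of pairs 2 bp apart. No biological explanation was tested, so methylation that differs between strands stays open, as does whether the authors merged strands.

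The overlap of hyper positions between iPSC 1 and gPSC 2 led that of every other pair. Kind of line gave no clear lead to the pairs other than this one. The iPSC pair held 32.85% in common, below the 34.5% to 35.2% of the other 3 mixed pairs by more than their spread. The gPSC pair lay within them. Set against independent lists, the iPSC pair (1.78 times) lay within those mixed pairs (1.71 to 1.82), and the gPSC pair was at 1.70. The low place of the iPSC pair thus depends on the measure, and these values do not decide on kind of line. Among 18023 positions with another listed within 10 bp in every line, the lead of iPSC 1 with gPSC 2 fell from 11.6 to 1.381 points. Within 5 bp it was gone (68.67% against 68.75% for iPSC 2 with gPSC 1). Coverage of the same positions in both libraries would give such a fall, though this selection raised all overlaps. The pair also led at positions 1 bp from an opposite one (18.35%), which a shared library or sequencing batch could give, of which the labels say nothing. Next there came the complementary pair, iPSC 2 and gPSC 1, with 16.1% against 10.9% to 13.3% for the other 4, as an exchange of labels between 1 iPSC and 1 gPSC line would give. Over all listed positions the complementary pair led those 4 by only 0.114 points, against 11.7 for the first pair, and without positions 1 bp from an opposite one it lay below the gPSC pair (36.6% and 36.9%). For hypo positions it lay below iPSC 1 with gPSC 1 (16.6% and 18.7%). Among the positions with another listed within 10 bp it held 65.61%, above 63.8% for the highest of the 4 but by less than their spread, while within 20 bp its lead of 1.99 points exceeded their spread (59.9% to 60.9%). As these rows go both ways and none lies past its spread against an exchange, exchanged labels and a batch cannot be told apart.

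Germline gene promoters were hyper in the pluripotent lines of both kinds. Positions within 50 bp of a listed opposite one are argued against as the only source, since without them the list lay at percentile 100 in both kinds of line, with 5 and 6 members called. A position whose opposite neighbour was not listed stays in, so a shift in strand balance cannot be excluded this way. A low level in the reference library alone would raise these promoters in every comparison, and 1 of the 7 promoters called in iPSC or gPSC was also hyper in GSC, while 5 had a listed position there and 3 of these a hypo one. GSC can differ at germline genes for reasons of its own, so a low level in the reference library and higher methylation in the lines cannot be told apart. As a hypothesis, germline genes may be more methylated in pluripotent lines made from germline cells than in this ESC line, and levels per library would decide it.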
